A study of Mus musculus with 40 samples.

How the data were processed

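RNA of bone marrow cells from 20 DBA/2 mice was measured on 40 arrays that take 2 dyes. DBA/2 is an inbred laboratory strain. The mice formed 4 groups of 5, namely untreated control mice and mice whose marrow was taken 1, 2 or 5 days after an intraperitoneal dose of 83 mg/kg cyclophosphamide, and the labels number the 5 mice of a group as biological replicates. Each mouse was hybridised on 2 arrays, which the labels call technical replicates. Per the labels' protocols, total RNA was extracted with a Qiagen RNeasy Midi kit and amplified with an Ambion amino allyl kit, the RNA of each mouse was labelled with Cy5, and a common reference was labelled with Cy3. The labels describe that reference as a pool of marrow from untreated mice, while its treatment field says that mice were given cyclophosphamide; which is right was not settled here. The reference cancels in differences between groups of mice, but the few values given against the pool depend on what the pool was.

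The authors' deposited values are 1 number per probe and array, taken here as log2 ratios of sample over reference. Their scanner, background correction, normalization and probe filter are not given in the sources used here. The direction follows from the dyes in the labels, which put every mouse in Cy5, and of the 780 pairs of arrays the lowest correlation was -0.175, with 0 pairs below -0.3. The values run from -4.8 to 2.67 and the array medians lie within 0.015 of 0, as after centring of each array. The log base and the step that did the centring stay unknown, and natural logarithms cannot be excluded, in which case every fold would be larger than stated.

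An entry of the platform annotation existed for 10202 of the 13443 probes. Of these, 10032 had 1 gene symbol and 170 had several, and 3241 probes had no entry. The symbols of 10028 of the probes with a single symbol matched a gene of the RefSeq table of the mouse, and current symbols were used. No genome was used, so no coordinates are given. Probes with several symbols or none were counted but not named. Many values were blank, between 40.7% and 69.7% of probes per array, and the rule that made them so is not given in the sources used here. No value was filled in, and no pseudocount was used.

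On 38 of the 40 arrays a set of probes, among them several for abundant transcripts such as globins and ribosomal proteins, shared 1 value to within 0.001, as spots at the limit of the scanner in both channels would. This value lay between -0.725 and -0.199, and 726 values (0.307% of all) were at it. Of the genes named, Hba-a1 was at it on 33 arrays, Ngp on 13, Rps6 on 10, Rps14 on 8, Actb on 2, and Ltf, Tpx2, Pgam1, Uqcrc1 and Plek on 1 each. Such probes are said to look saturated. The scanner's own marks are not given in the sources used here, and saturation in a single channel leaves no such trace. The values were kept, and an alternative added after the data had been seen left them out.

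The 2 arrays of a mouse were averaged, so that n counts mice, and probes with the same symbol were averaged after that, which left 13027 genes and unnamed probes. A gene or unnamed probe was tested when at least 3 mice of every group had a value. This left 5297, of which 3926 had a symbol and 1371 did not, and 256 of the named ones had several probes. The average can mix probes that were measured in different mice, as for Il1b. A linear model with 1 mean per group was fitted over all 20 mice in limma 3.58.1 under R 4.3.3, with empirical Bayes moderation (prior degrees of freedom 7.8, median moderated SD 0.2) and Benjamini-Hochberg adjustment, and calls were made at an adjusted p under 0.05. Standard errors of fold changes are those of this model. The moderated F test asked whether the 4 groups differed. Precision rests on 5 mice per group, and the median standard error of a fold change on day 1 was 0.13.

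For 40 gene lists, the 33 with at least 5 measured members were tested for a shift relative to all other genes with limma's camera method, in its pre-ranked form, at a preset correlation of 0.01. The planned form cannot take blank values. Adjustment was over the 33 lists within a comparison, and each call was computed again with an estimated correlation. The difference of list means between groups is given with its standard error over mice. The lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined. The rule named, for each day against control, the 10 largest rises and 10 largest falls among genes that passed and had all 5 treated mice on 1 side of the control mean, up to 4 passing members of each list described (where none passed, the member with the smallest p) and 22 fixed genes. Between days it named the 5 largest rises and the 5 largest falls. Of the 22 fixed genes 5 were measured well enough, 12 were measured in too few mice and 5 were not in the platform annotation.

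The steps were tested on simulated data. With 200 of 5297 genes changed between control and day 1 in 20 simulations, 60.5% of genes changed by 0.5 on the log2 scale were called, 99.2% of those changed by 1, 100% by 1.5 and 99.9% by 2, and 4.6% of the called genes were false. All of the 3 lists shifted by 0.5 were called (100%), as were 0.71% of the others. The simulated genes varied independently of each other, while genes of the real lists can vary together, so these rates need not hold for the real data. Alternatives tried were other scalings of the arrays, other minimum numbers of mice, the replicate number as a block, single arrays per mouse, all 40 arrays with the mouse as a random block, single probes, robust moderation, other thresholds, other list tests, fits of the compared groups alone and fits without each mouse in turn. A fit without a mouse kept the minimum of 3 mice per group and so tested fewer genes. Lists of few measured genes could go untested in it. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.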

Results

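Cyclophosphamide is a drug whose active metabolites cross-link DNA, and dividing marrow cells are among the cells it damages. The series asks how gene expression in mouse marrow differs between untreated mice and mice 1, 2 and 5 days after a dose of 83 mg/kg. Each group held 5 mice with 2 arrays each, 40 arrays in all. An array gave values for 4079 to 7977 of 13443 probes. The number of probes measured per mouse (mean ± SD, n = 5) was 6646.2 ± 1502 in control, 6331.2 ± 500.5 on day 1, 6452.2 ± 1158 on day 2 and 5776.6 ± 1107 on day 5. The 2 arrays of a mouse correlated across probes at 0.683 to 0.957 and shared 0 identical values. Mice of a group correlated on average at 0.399 in control, 0.505 on day 1, 0.665 on day 2 and 0.603 on day 5, with control mouse 4 (0.239) and day 1 mouse 1 (0.354) the least like their own groups. The first principal component held 41.3% of the variance over 2979 genes measured in all mice and set days 1 and 2 against control and day 5.

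Values below are log2 fold changes ± SE with 5 mice per group unless another number is given, on the assumption that the deposited ratios are base 2, and adjusted p values are from limma. A list mean stands for the difference between groups in the mean of the measured genes of a list. Across the 4 groups, 1626 of 5297 genes and unnamed probes differed by the moderated F test. Against control, 1012 passed on day 1 (568 higher, 444 lower), 1018 on day 2 (509 higher, 509 lower) and 139 on day 5 (48 higher, 91 lower). The change was at least 2-fold for 29, 59 and 32 of these.

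**Figure D1:**
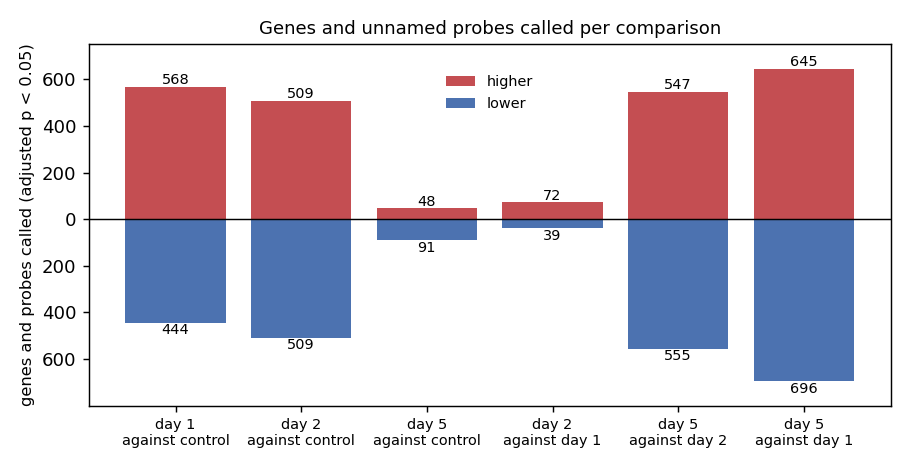
Number of genes and unnamed probes past an adjusted p of 0.05 in each comparison, with higher calls as bars above 0 and lower calls as bars below 0 (5 mice per group). Day 5 differed from control in 48 higher and 91 lower, against 568 and 444 on day 1.

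One day after the drug, targets of the tumour suppressor p53 had risen. Lists of mitosis, DNA replication, the respiratory chain, B cell precursors, and granulocyte precursors with primary granules were called lower, but all 5 calls were lost with an estimated correlation (adjusted p = 0.0908, 0.127, 0.127, 0.166 and 0.179). Of the B cell and granulocyte precursor genes only 2 of 5 each passed. Cdkn1a, which encodes the cell cycle inhibitor p21, rose by 1.63 ± 0.26 (3.1-fold, adjusted p = 0.000508), and was above the control mean in 5 of 5 mice. The sign of Cdkn1a was also the only check of direction among the 5 p53 targets set aside for it, since the other 4 were measured in too few mice or were not in the platform annotation. H2ax, the histone variant phosphorylated at DNA breaks, fell by 1.17 ± 0.14 on the log2 scale (adjusted p = 2.91e-05).

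Of 10 measured p53 targets, 5 rose, 0 fell and 5 did not pass, and 6 rose adjusted over the list alone. Besides Cdkn1a these included the stress-induced mTOR inhibitor Ddit4 (1.28 ± 0.29), the death receptor Tnfrsf10b (0.69 ± 0.15) and the translesion polymerase Polk (0.51 ± 0.13). The p53 target list mean was higher by 0.55 ± 0.08, in 5 of 5 mice (camera adjusted p = 0.00112, and adjusted p = 0.0102 with an estimated correlation).

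Mitosis genes fell, with 8 of 13 lower, 0 higher and 5 not passing, and 9 lower adjusted over the list alone. Cks2, a cofactor of cyclin-dependent kinases, changed by -1.17 ± 0.21, Ect2, needed for cytokinesis, by -0.99 ± 0.15, the spindle factor Tpx2 by -0.75 ± 0.15 and the kinase Cdk1 by -0.74 ± 0.15. The mitosis list mean was -0.53 ± 0.08 in 5 of 5 mice (adjusted p = 2.58e-05, but adjusted p = 0.0908 with an estimated correlation). In DNA replication 7 of 12 fell, 0 rose and 5 did not pass, and 9 fell adjusted over the list alone. Dut (-0.94 ± 0.16), which removes dUTP, the sliding clamp Pcna (-0.92 ± 0.13), the helicase subunit Mcm4 (-0.87 ± 0.15, 4 control mice) and the thymidylate synthase Tyms (-0.74 ± 0.14) led it. Its mean was -0.51 ± 0.08 in 5 of 5 mice (adjusted p = 2.58e-05, but adjusted p = 0.127 with an estimated correlation).

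Respiratory chain transcripts fell in 5 of 9 cases, with 0 higher and 4 not passing, and 7 fell adjusted over the list alone. Among them were Ndufa5 of complex I (-0.82 ± 0.23), Uqcrb (-0.76 ± 0.25) and Cyc1 (-0.67 ± 0.12) of complex III. The respiratory chain list mean was -0.47 ± 0.11 in 5 of 5 mice (adjusted p = 0.00143, but adjusted p = 0.127 with an estimated correlation). Of 8 cytosolic ribosomal protein genes 4 fell, 0 rose and 4 did not pass, and 5 fell adjusted over the list alone, led by Rpl28 (-0.84 ± 0.21) and Rps18 (-0.76 ± 0.19). That list's mean was -0.45 ± 0.20 (adjusted p = 0.0279, but adjusted p = 0.303 with an estimated correlation), and control mouse 3 stood at 0.771 against the pool, with the next control mouse at 0.123. Its member Rps6 looked saturated on 7 of 10 control arrays.

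B cell precursor transcripts fell for 2 of 5 genes, also 2 adjusted over the list alone, with 0 higher and 3 not passing. These were Vpreb1 (-1.15 ± 0.22) and Vpreb3 (-0.97 ± 0.28), parts of the surrogate light chain and its relatives. The B cell precursor list mean was -0.66 ± 0.14 in 5 of 5 mice (adjusted p = 0.0422, but adjusted p = 0.166 with an estimated correlation). Day 1 mouse 1 stood apart at 0.0123 against the pool, with the next mouse at -0.547, and for Vpreb3 at -0.0191 against -0.993. Of 5 granulocyte precursor genes 2 fell, also 2 adjusted over the list alone, 0 rose and 3 did not pass. The primary granule protease Prtn3 changed by -1.15 ± 0.23 and Plac8 by -0.66 ± 0.17. The granulocyte precursor list mean was -0.55 ± 0.14 in 5 of 5 mice (adjusted p = 0.0293, but adjusted p = 0.179 with an estimated correlation). Among 6 monocyte genes 2 fell, also 2 adjusted over the list alone, 0 rose and 4 did not pass. The transglutaminase F13a1 changed by -0.90 ± 0.11 and Ms4a6c by -0.61 ± 0.14 (4 control mice). The monocyte list mean was -0.41 ± 0.10 in 5 of 5 mice (adjusted p = 0.0293, but adjusted p = 0.166 with an estimated correlation).

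Some macrophage genes moved the other way on day 1. Of 5, 2 rose, 0 fell and 3 did not pass, while 5 rose adjusted over the list alone. The complement gene C1qb rose by 1.27 ± 0.31 and Adgre1, which encodes the F4/80 antigen, by 0.48 ± 0.12. The macrophage list mean rose by 0.64 ± 0.14 in 5 of 5 mice (adjusted p = 0.00954, but adjusted p = 0.127 with an estimated correlation). Some endothelial markers moved with them. Of 5, 2 rose, 0 fell and 3 did not pass, and 3 rose adjusted over the list alone, with Plvap at 0.80 ± 0.20 (4 control mice), Flt1 at 0.60 ± 0.15 and a list mean of 0.42 ± 0.06 in 5 of 5 mice (adjusted p = 0.0352, but adjusted p = 0.0908 with an estimated correlation). Of 8 stromal and bone-forming markers 2 rose, 3 adjusted over the list alone, led by the matricellular protein gene Fstl1 (0.85 ± 0.12). The stromal list mean was 0.31 ± 0.05 and did not pass (adjusted p = 0.0711).

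Other large changes on day 1 included rises of Alas2, the first enzyme of haem synthesis in red cell precursors (1.36 ± 0.21), the calcium-binding Anxa4 (1.11 ± 0.18), Syt9 (1.12 ± 0.20), Actb, which encodes cytoplasmic actin (1.06 ± 0.24), Snx24 (1.05 ± 0.21), Stimate (1.03 ± 0.18) and the kallikrein Klk1b5 (1.00 ± 0.20). Anxa4, Syt9, Snx24, Stimate and Klk1b5 varied alike across mice. Within their groups each was lowest in day 1 mouse 4, day 2 mouse 2 and day 5 mouse 4. Their rises may therefore not be separate results, and what they share was not tested. Falls included the glutathione transferase Mgst3 (-1.26 ± 0.25), the ATP synthase subunit Atp5j (-1.01 ± 0.17, 4 control mice), the leukotriene enzyme Lta4h (-0.97 ± 0.22, 4 control mice), the erythroid adhesion gene Icam4 (-0.96 ± 0.29) and Ppox, a later enzyme of haem synthesis (-0.93 ± 0.21). For Alas2, day 1 mouse 4 stood at 1.58 against the pool and the next at 0.701. Late neutrophil genes as a list gave -0.08 ± 0.12 (adjusted p = 0.823), the erythroid list -0.25 ± 0.10 (adjusted p = 0.261), the mature B cell list 0.44 ± 0.06 (adjusted p = 0.185) and the interferon-stimulated list 0.08 ± 0.08 (adjusted p = 0.622), whose median of -0.05 had the other sign. With an estimated correlation 1 of the 10 list calls held, that of the p53 targets. Without day 1 mouse 3 the number of genes and probes called was 611, without day 1 mouse 2 it was 641, and without control mouse 3 or day 1 mouse 4 the number of lists called was 5 or 6. These fits tested fewer genes, so a list of few genes could go untested.

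**Figure D2:**
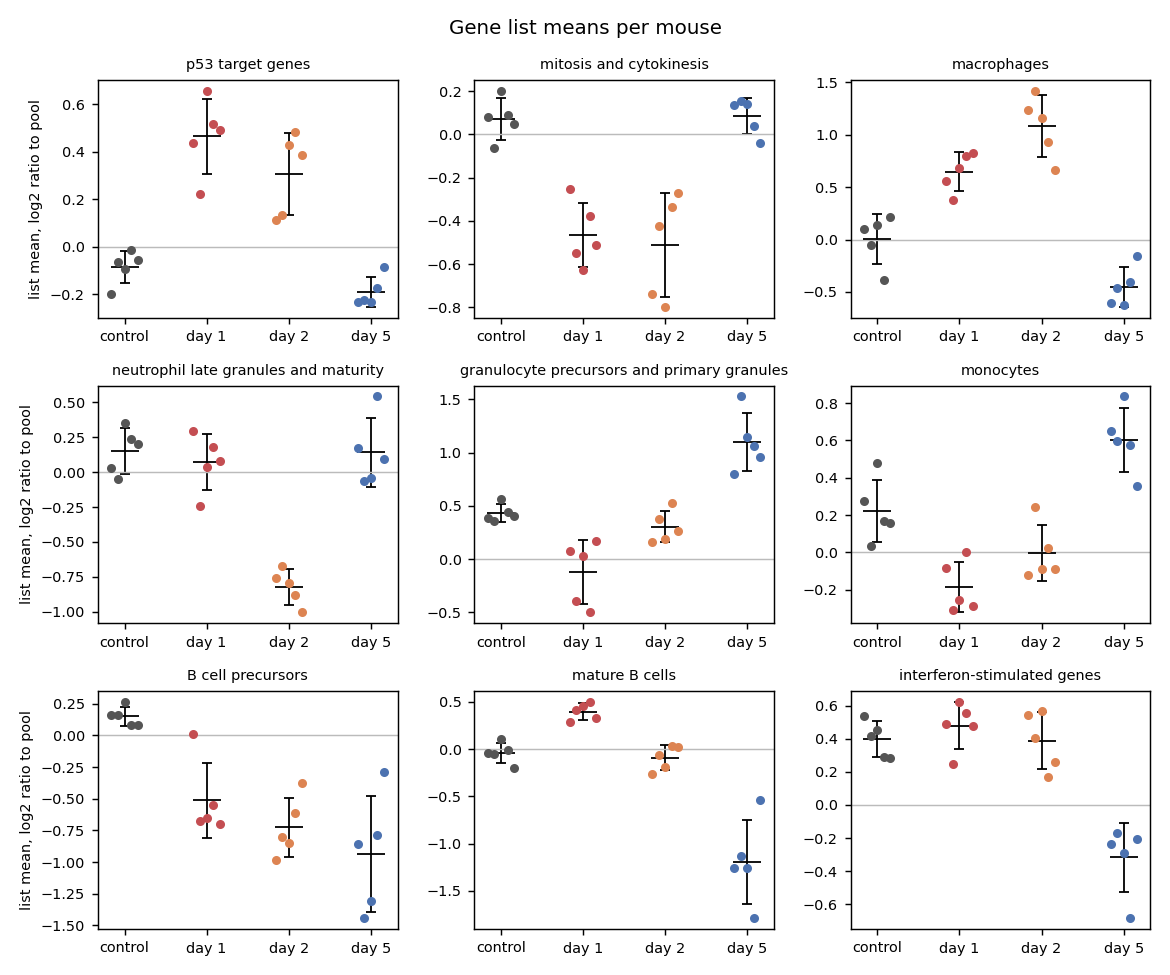
Mean log2 ratio to the pool of the measured genes of each list (y axis) in each group (x axis), with dots for mice, a black line for the mean and a bar for the SD (n = 5). The macrophage list was 1.08 higher than control on day 2 and the late neutrophil list changed by -0.97, while on day 5 the interferon-stimulated list changed by -0.71.

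On day 2, most measured genes of the list of late granules and maturity of neutrophils had fallen, and macrophage genes had risen. Mitosis genes were called lower and p53 targets higher, but both list calls were lost with an estimated correlation (adjusted p = 0.0566 and 0.109). Ltf, the lactoferrin of secondary granules, changed by -1.96 ± 0.19 (adjusted p = 1.39e-06) and was below the control mean in 5 of 5 mice. Siglec1, a sialic acid receptor of macrophages, rose by 1.19 ± 0.14 (adjusted p = 8.11e-06) and Cdkn1a by 1.70 ± 0.26 (adjusted p = 0.000144).

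Of 10 late neutrophil genes 7 fell, 0 rose and 3 did not pass, and 8 fell adjusted over the list alone. Besides Ltf they included Cd177 (-1.53 ± 0.16), a neutrophil surface protein, and S100a9 (-1.56 ± 0.29, 4 control and 3 day 2 mice), a subunit of calprotectin. They also included the secondary granule gene Ngp, which looked saturated on 6 of 10 control, 5 of 10 day 1 and 2 of 10 day 5 arrays, so that the size of its change cannot be read. The 3 members that did not pass were Mmp9 (-0.625 ± 0.242), Csf3r (0.279 ± 0.14) and Trem1 (0.107 ± 0.126). The fall was thus not shared by every measured gene of mature neutrophils. The late neutrophil list mean was -0.97 ± 0.09 in 5 of 5 mice (adjusted p = 1.76e-05, and adjusted p = 0.0303 with an estimated correlation). The list of granulocyte precursors and primary granules gave -0.13 ± 0.08 (adjusted p = 0.795), with 0 of 5 members called, and that of monocytes -0.23 ± 0.10 (adjusted p = 0.539), with 1 of 6 lower, the oxidase subunit Cybb (-1.11 ± 0.23).

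All 5 macrophage genes rose, 5 adjusted over the list alone too. C1qb rose by 1.34 ± 0.31, C1qa by 1.27 ± 0.25 (4 control mice) and the iron exporter Slc40a1 by 0.92 ± 0.18. For C1qb, day 2 mouse 5 stood at -0.0377 against the pool, within the control range of -0.911 to 0.25. The macrophage list mean rose by 1.08 ± 0.17 in 5 of 5 mice (adjusted p = 7.57e-06, and adjusted p = 0.00527 with an estimated correlation). Endothelial markers rose beside them, 3 of 5, with 0 lower, 2 not passing and 3 higher adjusted over the list alone. Plvap rose by 0.93 ± 0.20 (4 control mice), Flt1 by 0.65 ± 0.15 and Kdr by 0.62 ± 0.21. The endothelial list mean rose by 0.49 ± 0.04 in 5 of 5 mice (adjusted p = 0.0166, and adjusted p = 0.0303 with an estimated correlation). Of 8 stromal markers 2 rose, 2 adjusted over the list alone as well. These were Cxcl12, the chemokine that holds progenitors in the marrow (0.99 ± 0.31), and Fstl1 (0.92 ± 0.12). For Cxcl12, day 2 mice 4 and 5 stood at -0.386 and -0.21 against the pool, within the control range of -0.742 to -0.165. The stromal list mean was 0.34 ± 0.11 and did not pass (adjusted p = 0.0969). Of 5 megakaryocyte genes 2 rose, also 2 adjusted over the list alone, 0 fell and 3 did not pass. The integrin Itga2b rose by 1.00 ± 0.18 and the platelet chemokine Ppbp by 0.90 ± 0.21. The megakaryocyte list mean was 0.55 ± 0.16 in 5 of 5 mice (adjusted p = 0.0272, but adjusted p = 0.151 with an estimated correlation).

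Mitosis genes fell for 8 of 13, with 0 higher, 5 not passing and 10 lower adjusted over the list alone. Nusap1, a spindle protein, changed by -1.01 ± 0.14, Ect2, needed for cytokinesis, by -0.83 ± 0.15 and Cdca8 by -0.79 ± 0.20. The mitosis list mean was -0.58 ± 0.12 in 5 of 5 mice (adjusted p = 2.23e-05, but adjusted p = 0.0566 with an estimated correlation). Of 12 replication genes 4 fell, 0 rose and 8 did not pass, and 6 fell adjusted over the list alone. Among them were Pcna (-0.81 ± 0.13), Tyms (-0.64 ± 0.14) and the thymidine kinase Tk1 (-0.63 ± 0.14). The replication list mean was -0.36 ± 0.10 in 5 of 5 mice (adjusted p = 0.00509, but adjusted p = 0.249 with an estimated correlation). Of the 10 p53 targets 5 rose, 0 fell and 5 did not pass, while 5 rose and 1 fell adjusted over the list alone. The p53 target list mean was higher by 0.39 ± 0.08 in 5 of 5 mice (adjusted p = 0.0359, but adjusted p = 0.109 with an estimated correlation).

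Some red cell and B cell precursor genes were lower on day 2. Of 10 erythroid genes 4 fell, also 4 adjusted over the list alone, 0 rose and 6 did not pass. The membrane skeleton gene Ank1 changed by -1.01 ± 0.25 and the blood group genes Rhd and Kel by -0.95 ± 0.28 and -0.94 ± 0.23. The erythroid list mean was -0.45 ± 0.04 in 5 of 5 mice (adjusted p = 0.0359, but adjusted p = 0.28 with an estimated correlation). Of the Rhd probes measured in both groups, 1 gave -1.69 and the other -0.17 (4 control mice). The globin gene Hba-a1, 1 of the 10, looked saturated on 33 of the 40 arrays, so neither a change nor its absence can be read from it. Alas2 was at 0.58 ± 0.21 (adjusted p = 0.06). Of 5 B cell precursor genes 2 fell, 0 rose and 3 did not pass, and 4 fell adjusted over the list alone, with Vpreb3 at -1.51 ± 0.28, Vpreb1 at -1.05 ± 0.23 (4 day 2 mice) and a list mean of -0.88 ± 0.11 in 5 of 5 mice (adjusted p = 0.0272, but adjusted p = 0.129 with an estimated correlation).

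Other large rises on day 2 were those of Actb (1.19 ± 0.24), the ficolin Fcna (1.19 ± 0.19), Snx24 (1.11 ± 0.21), Anxa4 (1.09 ± 0.18), the complement inhibitor Serping1 (1.08 ± 0.12), Syt9 (1.06 ± 0.20) and Fxyd6 (1.06 ± 0.22). Large falls were those of Mgst3 (-2.00 ± 0.25), Btnl10 (-1.72 ± 0.26), Ppox (-1.59 ± 0.21), Icam4 (-1.31 ± 0.29), the chromatin protein Hmgn2 (-1.29 ± 0.18) and the histone chaperone Asf1b (-1.25 ± 0.18). With an estimated correlation 3 of the 9 list calls held, those of the late neutrophil, macrophage and endothelial lists. Without day 2 mouse 1 the number of genes and probes called was 592, and without day 2 mouse 2 or day 5 mouse 5 the number of lists called was 5. Here too fewer genes were tested, so a list of few genes could go untested.

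Fewer genes differed from control on day 5 than on days 1 and 2. Interferon-stimulated genes, B cell genes and several cytokines had fallen, while granulocyte precursor and monocyte genes had risen. Rtp4, an interferon-induced chaperone, changed by -1.99 ± 0.18 (adjusted p = 1.23e-07) and Ms4a1, which encodes the B cell antigen CD20, by -1.78 ± 0.40 (adjusted p = 0.0116), while Prtn3 rose by 1.35 ± 0.23 (adjusted p = 0.000914). Each of the 3 was on 1 side of the control mean in 5 of 5 mice. Mitosis (0.02 ± 0.06, adjusted p = 0.866), DNA replication (-0.04 ± 0.05, adjusted p = 0.655) and p53 target (-0.11 ± 0.04, adjusted p = 0.186) lists did not pass, and Cdkn1a was at 0.27 ± 0.26 (adjusted p = 0.851). Of 10 p53 targets 1 fell, also 1 adjusted over the list alone, 0 rose and 9 did not pass. That 1 was Trp53inp1 (-0.96 ± 0.17, adjusted p = 0.00266, 4 mice per group).

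Of 12 interferon-stimulated genes 5 fell, 0 rose and 7 did not pass, and 9 fell adjusted over the list alone. Beside Rtp4 they included Ifi27l2a (-1.66 ± 0.27), the guanylate-binding protein Gbp2 (-1.25 ± 0.16) and the transcription factor Irf9 (-0.81 ± 0.15, 4 mice per group). The interferon-stimulated list mean was -0.71 ± 0.11 in 5 of 5 mice (adjusted p = 9.37e-15, and adjusted p = 0.000246 with an estimated correlation). Day 5 mouse 4 was lowest at -0.682 against the pool, with the next mouse at -0.291. The control mice stood 0.40 ± 0.11 (SD, n = 5) above the pool for this list, and the labels leave open whether that pool was untreated. Of 9 genes of antigen presentation by MHC class I 3 fell, 0 rose and 6 did not pass, with 2 higher and 3 lower adjusted over the list alone, and these were the peptide transporter Tap1 (-0.96 ± 0.14, 4 mice per group), the class I heavy chain H2-D1 (-0.81 ± 0.18, 4 day 5 mice) and the proteasome subunit Psmb10 (-0.40 ± 0.10). That list's mean was -0.24 ± 0.08 in 5 of 5 mice (adjusted p = 0.0168, but adjusted p = 0.205 with an estimated correlation), and the control mice stood 0.32 ± 0.14 (SD, n = 5) above the pool.

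Of 6 mature B cell genes 3 fell, 0 rose and 3 did not pass, and 5 fell adjusted over the list alone. Besides Ms4a1 they were Ly6d (-1.10 ± 0.20, 4 mice per group) and the inhibitory receptor Cd22 (-0.99 ± 0.13). The mature B cell list mean was -1.15 ± 0.21 in 5 of 5 mice (adjusted p = 3.63e-09, and adjusted p = 2.6e-09 with an estimated correlation). The estimated correlation thus did not make the test of this list stricter. In an exact permutation test of its mean over mice, p was 0.00794 and adjusted p 0.0397. Of 5 B cell precursor genes 2 fell, 0 rose and 3 did not pass, and 4 fell adjusted over the list alone, with Vpreb3 at -1.72 ± 0.28, Vpreb1 at -1.11 ± 0.22 and a list mean of -1.09 ± 0.21 in 5 of 5 mice (adjusted p = 3.16e-06, and adjusted p = 0.000343 with an estimated correlation). The secretory protein Mzb1 of B and plasma cells changed by -1.95 ± 0.28 and the class II gene H2-Aa by -1.34 ± 0.18.

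Among 5 cytokines and chemokines 3 fell, 0 rose and 2 did not pass, with 1 higher and 3 lower adjusted over the list alone. These were interleukin 1 beta, Il1b (-1.88 ± 0.30), its antagonist Il1rn (-1.09 ± 0.21) and Ccl6 (-1.15 ± 0.27, 3 day 5 mice). The cytokine list mean was -0.81 ± 0.19 in 5 of 5 mice (adjusted p = 0.00178, and adjusted p = 0.00597 with an estimated correlation). The probe of Il1b that was measured in control mice gave -2.21. The macrophage list was at -0.46 ± 0.14 in 5 of 5 mice (adjusted p = 0.00243, but adjusted p = 0.0533 with an estimated correlation), with 0 of 5 members called and 4 lower adjusted over the list alone.

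Of 5 granulocyte precursor genes 2 rose, 0 fell and 3 did not pass, and 4 rose adjusted over the list alone. Prtn3 and the cystatin Cst7 (0.72 ± 0.16, 4 control mice) were the 2. The granulocyte precursor list mean was higher by 0.67 ± 0.13 in 5 of 5 mice (adjusted p = 8.71e-06, and adjusted p = 0.00394 with an estimated correlation). Of 6 monocyte genes 3 rose, also 3 adjusted over the list alone, 0 fell and 3 did not pass. F13a1 rose by 0.84 ± 0.11, Ms4a6c by 0.62 ± 0.14 (4 control mice) and Emb by 0.52 ± 0.12. The monocyte list mean rose by 0.38 ± 0.11 in 5 of 5 mice (adjusted p = 0.000293, and adjusted p = 0.0151 with an estimated correlation). The late neutrophil list was at -0.01 ± 0.13 (adjusted p = 0.655), with a median of 0.07 of the other sign. Of its 10 genes 2 fell, also 2 adjusted over the list alone, the gelatinase Mmp9 (-0.98 ± 0.26, 4 day 5 mice) and the receptor Csf3r (-0.57 ± 0.14).

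Other large rises on day 5 were those of Dmkn (2.08 ± 0.20), Zcchc18 (1.17 ± 0.21), the B cell survival factor Tnfsf13 (1.12 ± 0.15), the creatine enzyme Gatm (0.96 ± 0.17), the proteoglycan Gpc1 (0.89 ± 0.14), Ifitm2 (0.87 ± 0.20), B4galt6 (0.86 ± 0.18) and Mpst (0.78 ± 0.18). Large falls were those of Cyp4f18, a leukotriene hydroxylase of neutrophils (-2.32 ± 0.27), and the sodium pump subunit Atp1b1 (-1.70 ± 0.20). With an estimated correlation 6 of the 8 list calls held. The number of lists called was 4 without day 1 mouse 2 or day 1 mouse 3, and 5 without day 1 mouse 4 or day 5 mouse 5. Day 1 mice are not part of this comparison, but fits without them tested fewer genes. Lists with 5 measured genes could then go untested, so a lower count need not mean a weaker change.

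**Figure D3:**
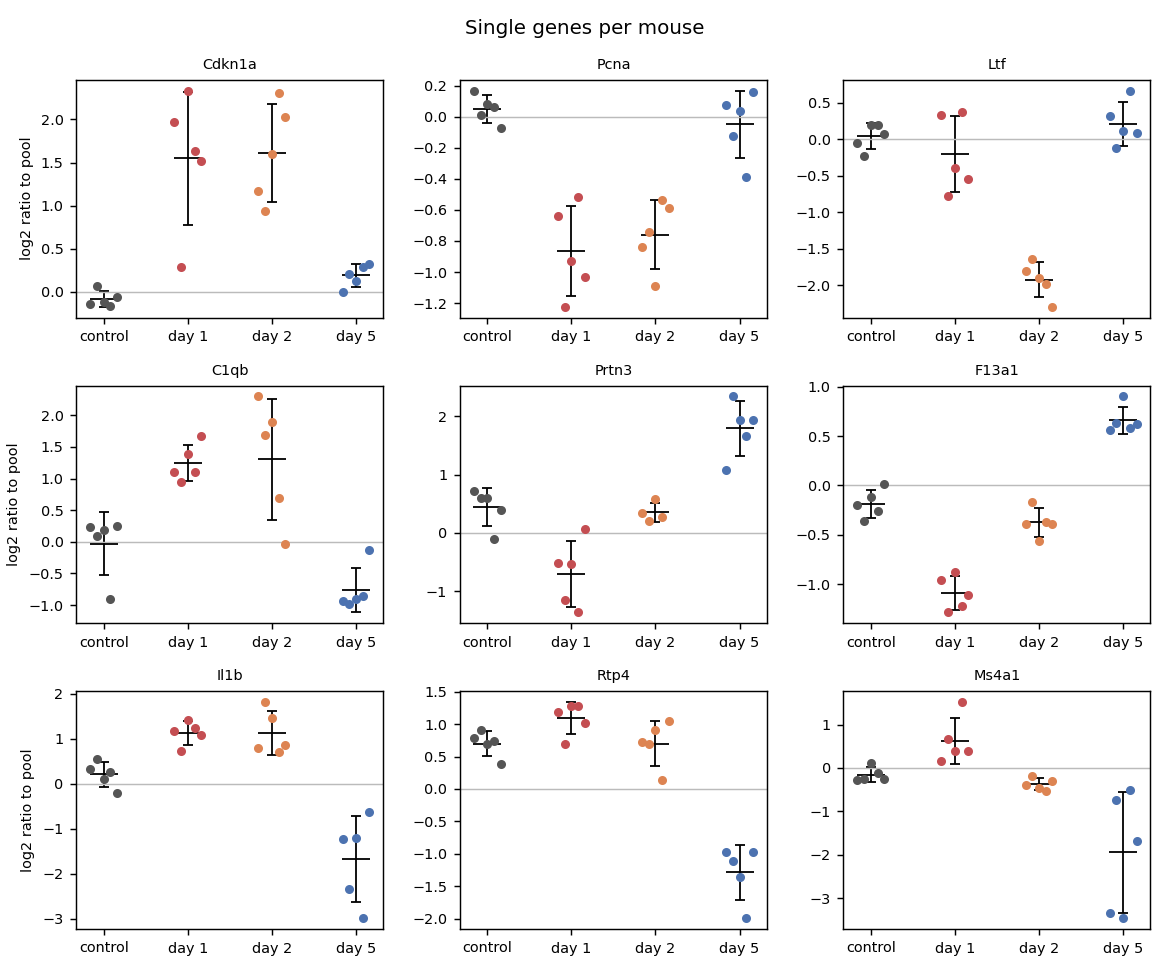
Log2 ratio to the pool of single genes (y axis) in each group (x axis), with dots for mice, a black line for the mean and a bar for the SD (n is 5 mice where all were measured). Cdkn1a was 1.63 above control on day 1 and 1.70 on day 2, and 0.27 on day 5.

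Between day 1 and day 2 the direct comparison called 111 genes and probes (72 higher on day 2, 39 lower), and the late neutrophil list fell. Of its 10 genes 5 fell, 0 rose and 5 did not pass, and 7 fell adjusted over the list alone. Ltf changed by -1.72 ± 0.19, Cd177 by -1.29 ± 0.16 and S100a9 by -1.22 ± 0.28 (3 day 2 mice). The late neutrophil list mean changed by -0.89 ± 0.11 in 5 of 5 mice (adjusted p = 1.43e-12, and adjusted p = 0.000116 with an estimated correlation). Ribosome biogenesis genes rose, 4 of 9 with 0 lower and also 4 adjusted over the list alone, among them Rrs1 (0.83 ± 0.17, 3 day 1 mice). The ribosome biogenesis list mean was 0.33 ± 0.06 in 5 of 5 mice (adjusted p = 8.18e-05, and adjusted p = 0.00272 with an estimated correlation). The macrophage list rose by 0.44 ± 0.16 (adjusted p = 0.00083, and adjusted p = 0.0425 with an estimated correlation), with Siglec1 at 0.90 ± 0.14 the 1 of 5 called and 2 higher adjusted over the list alone. In an exact permutation test of list means over mice, the macrophage list had p = 0.0397 and adjusted p = 0.238. No list passed this test from day 1 to 2 (lowest adjusted p = 0.106). The late neutrophil, ribosome biogenesis and mature B cell lists each had p = 0.00794 in it, the smallest that 5 mice against 5 allow. With so few lists at that limit, adjustment over all lists gave 0.106, so the test could not decide on these lists. The galectin Lgals1 rose by 1.49 ± 0.21 (4 day 1 mice), Prtn3 by 1.06 ± 0.24 (4 day 2 mice) and Krtcap2 by 0.93 ± 0.18, and Ncoa4, the ferritin receptor of autophagy, changed by -1.05 ± 0.18. The mature B cell list was lower by a difference of -0.49 ± 0.07 in 5 of 5 mice (adjusted p = 0.0221, and adjusted p = 0.0425 with an estimated correlation), with 0 of 6 members called and 1 lower adjusted over the list alone. In a fit of these 2 groups alone 52 were called, and without day 5 mouse 4 the count was 167.

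From day 2 to day 5, 1102 genes and probes differed (547 higher on day 5, 555 lower), and several lists called on day 2 were called in the opposite direction. Both comparisons hold the same day 2 mice, with opposite sign, so an opposite call is not a result independent of the day 2 call. Of 10 late neutrophil genes 7 rose and 1 fell, and 7 rose and 2 fell adjusted over the list alone. Ltf rose by 2.13 ± 0.19 and S100a9 by 1.93 ± 0.29 (3 day 2 and 4 day 5 mice), while Csf3r changed by -0.85 ± 0.14. The late neutrophil list mean was 0.96 ± 0.12 in 5 of 5 mice (adjusted p = 0.00105, but adjusted p = 0.0563 with an estimated correlation). All 5 macrophage genes fell, 5 adjusted over the list alone too, with C1qb at -2.07 ± 0.31, C1qa at -1.92 ± 0.25 (4 day 5 mice) and a list mean of -1.53 ± 0.16 in 5 of 5 mice (adjusted p = 5.62e-08, and adjusted p = 0.000363 with an estimated correlation). Mitosis genes rose, 8 of 13 with 0 lower and 9 adjusted over the list alone, by 0.60 ± 0.11 (adjusted p = 6.82e-05, and adjusted p = 0.0429 with an estimated correlation). Il1b changed by -2.79 ± 0.30 (-3.66 for the probe measured in every mouse), Cyp4f18 by -2.22 ± 0.27 and Rtp4 by -1.99 ± 0.18, while Tnfsf13 rose by 1.99 ± 0.15 and Hmgn2 by 1.94 ± 0.18. Endothelial markers fell with the macrophage genes, 3 of 5 and also 3 adjusted over the list alone, with a difference of -0.50 ± 0.06 (adjusted p = 0.011, and adjusted p = 0.0276 with an estimated correlation), and the stromal list was at -0.42 ± 0.11 (adjusted p = 0.045, but adjusted p = 0.0693 with an estimated correlation), with 3 of 8 lower. Interferon-stimulated genes fell, 7 of 12 and also 7 adjusted over the list alone, with a list mean of -0.70 ± 0.12 in 5 of 5 mice (adjusted p = 2.8e-06, and adjusted p = 0.0313 with an estimated correlation).

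From day 1 to day 5, 1341 genes and probes differed (645 higher on day 5, 696 lower). Granulocyte precursor genes rose, 4 of 5 with 0 lower and 5 adjusted over the list alone, led by Prtn3 (2.50 ± 0.23). The granulocyte precursor list mean was 1.22 ± 0.18 in 5 of 5 mice (adjusted p = 9.18e-05, and adjusted p = 0.0163 with an estimated correlation). The monocyte list rose by 0.79 ± 0.10 in 5 of 5 mice (adjusted p = 0.000294, and adjusted p = 0.0236 with an estimated correlation), with F13a1 at 1.75 ± 0.11. Mature B cell genes fell, 5 of 6 and also 5 adjusted over the list alone, with Ms4a1 at -2.57 ± 0.40, the receptor Fcmr at -2.19 ± 0.51 and a list mean of -1.59 ± 0.20 in 5 of 5 mice (adjusted p = 5.25e-05, and adjusted p = 5.98e-05 with an estimated correlation). For Fcmr, day 5 mouse 4 stood at -4.75 against the pool and the next at -1.42. Of 10 p53 targets 8 fell, and 9 adjusted over the list alone. The p53 target list mean was -0.65 ± 0.08 in 5 of 5 mice (adjusted p = 9.18e-05, and adjusted p = 0.000747 with an estimated correlation). Il1b changed by -2.80 ± 0.30 (-3.16 for that probe), Cyp4f18 by -2.74 ± 0.27 and Rtp4 by -2.38 ± 0.18, and Dmkn rose by 1.79 ± 0.20 and Tnfsf13 by 1.69 ± 0.15.

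Days 1 and 2 shared 582 genes and probes that were called in the same direction against control, 366 higher and 216 lower, and 3 were called in opposite directions. Independent lists of these sizes would share 54.6 higher and 42.7 lower. Unchanged groups, simulated as independent noise with a common control group, shared 0. Such groups call few genes and so can share few, which also limits the simulated counts given below. The fold changes of both days correlated across genes at 0.776, against 0.501 from the shared controls alone, and genes are not independent replicates. Their covariance was 0.0813 against a simulated 0.0105, a difference of 0.0708, and with the controls split between the days the correlation had a median of 0.631 over 20 splits. Days 1 and 5 shared 16 calls of 1 direction and 28 of opposite direction, where independent lists would give 5.15 higher, 7.63 lower and 13.8 opposite and unchanged groups 0.01, with a correlation of 0.0255 against a simulated 0.498 and a covariance of 0.00192 against 0.0105. Days 2 and 5 shared 42 of 1 direction and 8 opposite, where independent lists would give 4.61, 8.74 and 13.4 and unchanged groups 0, with a correlation of 0.195 against 0.497 and a covariance of 0.0153 against 0.0106. In all 3 comparisons 12 genes and probes were called the same way, 1 higher and 11 lower. Among them, chosen for naming after their values were seen, the peroxidase Gpx3 was higher (0.51 ± 0.13, 0.64 ± 0.13 and 0.49 ± 0.13 on days 1, 2 and 5) and Vpreb1, Vpreb3 and Psmb10 were lower. With the controls split between the days, the shared calls had medians of 88, 2 and 12, from fits with fewer control mice.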

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

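The tests of array scaling, of the level of the day 5 mice against the pool, of the interferon list from day 2 to day 5, of fewer neutrophils, of granule genes without Ngp and of an alike rise of resident cell types were chosen only after their results had been seen. The other tests of this part were set before.

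Interferon-stimulated genes were lower on day 5 than in control mice by -0.71 ± 0.11 as a list, and array scaling as the cause is argued against by the value after quantile normalization, -0.867 ± 0.113 (exact permutation test on the list mean, two-sided, p = 0.00794, the smallest that 5 mice against 5 allow). Control mice stood at 0.396 ± 0.0485 (SE, n = 5) against the pool and day 5 mice at -0.316 ± 0.0936, but the labels do not settle whether the pool was untreated. Without use of the pool, a high level in the control mice as the whole cause is argued against by the change of -0.704 ± 0.122 from day 2 to day 5 (exact permutation test, two-sided, p = 0.00794), with days 1 and 2 differing from control by 0.0808 ± 0.0799 and -0.00814 ± 0.0915, and whether it adds to the pattern stays open. A loss of B cells that carry these transcripts could contribute and stays open, because with the mature B cell list as a covariate over 20 mice the difference was -0.418 ± 0.21 and the slope 0.255 ± 0.16. A response of the marrow to the drug at day 5 also stays open and was not tested apart from these.

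The granule genes Ltf and Cd177 were near control on day 5 (0.17 ± 0.19 and 0.07 ± 0.16) while Il1b, Cyp4f18, Csf3r, Mmp9, Ccl6 and Il1rn were low. Fewer neutrophils could be part of this and stay open, because the mean of Ltf, Ngp and Cd177 (0.11 ± 0.0943, exact permutation test, two-sided, p = 0.238) holds Ngp, which looked saturated on 6 of 10 control arrays, and without it the mean (0.122 ± 0.0975, exact p = 0.254) rests on 2 genes that belong to the pattern, of which Ltf looked saturated on 1 of 10 control arrays. The hypothesis of a younger neutrophil pool predicted that other late genes, of which Fpr2, Trem1, Clec4e and Gda were measured, would be lower than the secondary granule genes. That difference was -0.114 ± 0.155 (exact permutation test, two-sided, p = 0.468), or -0.127 ± 0.103 without Ngp (exact p = 0.222), so the prediction was not met, but with 4 and 2 genes the hypothesis is not excluded. The mean of the 4 other late genes differed from control by -0.00447 ± 0.131 on day 5, but it had not followed the granule genes on day 2 either (-0.0743 ± 0.068). Of the 4, Fpr2 alone fell on day 2 (-0.676 ± 0.169) and was at 0.056 ± 0.169 on day 5. With 1 such gene, they do not decide between these.

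Macrophage genes were higher on day 2 than in control mice by 1.08 ± 0.17 as a list. A larger share of every cell type that did not die would raise the macrophage list as much as the endothelial, stromal, T cell and adipocyte lists, but the macrophage list rose more, by 0.763 ± 0.146 (exact permutation test, two-sided, p = 0.00794), against 0.316 ± 0.0607 for the mean of those 4. Whether T cells were spared by the drug was not measured, and the adipocyte list held fewer than 5 measured genes. The difference therefore argues only against an equal rise of these lists. More stroma and vessel tissue in the flushed marrow could contribute and stays open, because with the stromal and endothelial mean as a covariate over 20 mice the difference was 0.458 ± 0.251 and the slope 1.49 ± 0.527. A change in the number or state of macrophages after the drug stays open too, and was not tested apart from these.

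Among 838 groups of 5 or 4 mice looked at for a mouse far from the others (values of named genes, list means and array measures), 67 had a gap to the nearest mouse above Dixon's critical share of the group's range. Chance flags about 1 in 20 groups, which would be 41.9. Of 666 groups of gene values there were 57, where chance gives 33.3, of 160 groups of list means 8, where chance gives 8, and of 12 groups of array measures 2, where chance gives 0.6. The mice most often concerned were day 5 mouse 4 with 18 and control mouse 3 with 8. The shares of the range that follow carry no explanation.

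In control, mouse 3 was highest for Adipoq (0.792), Aldoa (0.785), Cks2 (0.721), Rpl28 (0.836), Rps6 (0.8) and the cytosolic ribosomal protein list (0.868), and lowest for Lamp1 (0.921) and Prdm1 (0.737). Control mouse 4 was lowest for C1qb (0.86), Dmkn (0.749), Fstl1 (0.924), Mpst (0.733) and Serping1 (0.775) and highest for Casp2 (0.859). Control mouse 5 was lowest for Alas2 (0.722), mouse 2 lowest for Mcm4 (0.932), and mouse 1 highest for the list of oxidative stress and detoxification (0.933). On day 1, mouse 4 was highest for Alas2 (0.765), Ccl6 (0.89), Mmp9 (0.774) and the osteoclast list (0.827) and lowest for Fstl1 (0.915), Krtcap2 (0.763) and Ndufa5 (0.778). Day 1 mouse 1 was highest for Mpst (0.803), Vpreb3 (0.791) and the B cell precursor list (0.782) and lowest for Itga2b (0.804), and day 1 mouse 2 was lowest for Calr (0.909).

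On day 2, mouse 1 was lowest for Dgat2 (0.75), Rpl28 (0.712), Rps3 (0.775), Rps6 (0.717) and the cytosolic ribosomal protein list (0.714), mouse 4 was highest for Adgre1 (0.918) and Cst7 (0.764), mouse 5 for H2ax (0.823) and mouse 3 for Hba-a1 (0.731). Rps6 and Hba-a1 looked saturated on 10 and 33 of the 40 arrays, which limits what their values show. Day 5 mouse 4 was lowest for the erythroid list (0.897) and for genes of red cells among others, namely Ank1 (0.94), Btnl10 (0.876), Fcmr (0.734), Icam4 (0.796), Irf9 (0.891), Kel (0.741), Mgst3 (0.786), Pgam1 (0.75), Ppox (0.769), Snx24 (0.821), Tspo2 (0.952) and the interferon-stimulated list (0.763). It was highest for Aldoa (0.839), B4galt6 (0.798), Uqcrc1 (0.767), Zfp36 (0.825) and the adipocyte list (0.742). Day 5 mouse 5 was highest for C1qa (0.94), C1qb (0.845), Mzb1 (0.843) and the number of probes measured on either array (0.787), and lowest for Cdca8 (0.747) and the correlation of its 2 arrays (0.716). Day 5 mouse 3 was highest for F13a1 (0.785) and H2ax (0.8), and day 5 mouse 1 lowest for Lgals1 (0.861), Nkg7 (0.869) and Rpl28 (0.789).

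Some genes and lists were called against control in opposite directions on 2 days, and their differences between the days are given below. Each passed (limma, or camera for lists), but this adds no support. For genes a passing difference was a condition of being given here, and for lists the choice of 2 opposite calls nearly fixes that outcome. From day 1 to day 5 the difference was -1.51 for Cd22, 0.93 for Cd63, -0.984 for Csf3r, 1.75 for F13a1, 1.33 for Gpc1, -2.07 for H2-Aa, -2.8 for Il1b (-3.16 for its probe measured in every mouse), 1.23 for Ms4a6c, -1.26 for Oasl2, 2.5 for Prtn3 and 1.69 for Tnfsf13. For list means it was 1.22 for granulocyte precursors, 0.79 for monocytes and -1.1 for macrophages. The day 1 calls of these 3 lists against control were lost with an estimated correlation (adjusted p = 0.179, 0.166 and 0.127), as was the day 5 call of macrophages (adjusted p = 0.0533). From day 2 to day 5 it was -1.37 for Cd22, 1.53 for Gpc1, -2.79 for Il1b (-3.66 for that probe), -1.1 for Oasl2, 1.99 for Tnfsf13 and -1.53 for the macrophage list. From day 1 to day 2 it was 1.49 for Lgals1, -1.06 for Ncoa4 and 0.783 for the peroxiredoxin Prdx1.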

How the results depend on the processing

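The fits without control mouse 4 and day 1 mouse 1, those without values shared by bright probes of an array, the list alternatives for differences between days and the fits of shared calls without single mice were chosen after the data had been seen. Of 9288 values of 277 named gene results under the alternatives, 8598 stayed on their side of the threshold, 639 lost the call, 51 gained it and 0 reversed. Of 5106 values of 198 list results, 4951 stayed, 122 lost the call, 33 gained it and 0 reversed. Genes and lists that an alternative left untested gave no value, so a call that dropped out of testing is not among those lost. Median centring, quantile normalization, other minimum numbers of mice, single arrays, single probes and robust moderation moved no count of genes by more than 1.5 times. Without control mouse 4 and day 1 mouse 1 the counts were 1184, 995 and 124 on days 1, 2 and 5. Without the values that bright probes shared they were 1019, 1033 and 139, no list or named gene crossed the threshold, and Ngp, Hba-a1 and Rps6 were left in too few mice to be tested. Signal over background is not given in the sources used here, so what it limits was not tested.

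The replicate numbers did not meet the rule for pairing, a correlation over 0.1 of the deviations in every same-numbered pair of mice. Between control and day 1, 3 of 5 pairs were over it (mean 0.131, lowest -0.00262, mean of other pairs -0.0324), between days 2 and 5, 4 of 5 (0.159, -0.0259 and -0.0423), and between the other groups 0 or 1 of 5. The replicate block changed the counts to 998 on day 1, 992 on day 2 and 134 on day 5.

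Stricter thresholds leave fewer genes by construction. At an unadjusted p under 0.001 the counts were 434 on day 1, 475 on day 2, 595 from day 2 to 5, 672 from day 1 to 5 and 836 among the 4 groups. With at least a 2-fold change they were 29 on day 1, 59 on day 2, 32 on day 5, 11 from day 1 to 2, 116 from day 2 to 5 and 122 from day 1 to 5. At an adjusted p under 0.01 the shared calls were 204 for days 1 and 2, 4 for days 1 and 5 and 23 for days 2 and 5, and with controls split, in fits with fewer control mice, 88, 2 and 12. All 40 arrays with the mouse as a random block gave 210 on day 5 and 241 from day 1 to 2, and a fit of days 1 and 2 alone gave 52; the cause was not tested.

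With an estimated correlation 1 list was called on day 1, 3 on day 2, 4 from day 1 to 2 and 6 from day 1 to 5. With fry 4 were called on day 1, 2 on day 5, 4 from day 1 to 2 and 7 from day 2 to 5. Fry used only genes measured in all 20 mice, which leaves fewer lists to test. Of the list results it covered, 79 stayed on their side of the threshold, 3 lost the call and 8 gained it. With members measured in all 20 mice, which leaves fewer lists to test, the counts were 4 on day 1, 4 on day 2, 1 on day 5, 4 from day 1 to 2, 5 from day 2 to 5 and 6 from day 1 to 5. An exact permutation test of list means over mice did not pass for some lists that camera called against control. These were the ribosomal protein list on day 1 (adjusted p = 0.0722) and, on day 5, MHC class I (adjusted p = 0.0793), macrophages and monocytes (adjusted p = 0.0636 each). The same test passed for some lists that camera did not call. Among these were stem and progenitor cells (adjusted p = 0.0244 on day 1 and 0.0212 on day 2) and stromal cells (0.0244 and 0.0335). Others were mature B cells on day 1 (0.0244), apoptosis on day 2 (0.0212) and T cells on day 5 (0.0397).

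Leaving out each mouse in turn gave 611 (without day 1 mouse 3) to 1313 calls on day 1, with 641 without day 1 mouse 2, 592 (without day 2 mouse 1) to 1123 on day 2, and 77 to 167 (without day 5 mouse 4) from day 1 to 2. Lists called ran from 5 (without control mouse 3, and 6 without day 1 mouse 4) to 10 on day 1, from 5 (without day 2 mouse 2 or day 5 mouse 5) to 10 on day 2, from 4 (without day 1 mouse 2 or 3, and 5 without day 1 mouse 4 or day 5 mouse 5) to 9 on day 5, and from 4 (without day 1 mouse 2 or 3) to 10 from day 1 to 2. Shared calls ran from 365 (without day 1 mouse 3, and 381 without day 2 mouse 1) to 727 for days 1 and 2 and from 9 (without control mouse 4) to 22 for days 1 and 5. The other counts stayed within 1.5 times, among them 100 to 161 on day 5. These fits tested fewer genes and probes, for example 4929 without day 1 mouse 2 and 4554 without day 5 mouse 5, against 5297 with all mice. Lists with 5 measured genes could drop below the 5 needed and go untested, which can lower the counts of lists. How much of the changes this explains was not tested.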

Other observations

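The counts in splits of the mice were planned before their results were seen, and the values of single probes and of genes outside the naming rule were looked up afterwards.

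Enzymes of haem synthesis moved apart on day 1, when Alas2 rose by 1.36 ± 0.21 and Ppox changed by -0.93 ± 0.21 (limma adjusted p = 0.000474 and 0.00486). As a list of 7 genes, haem synthesis and erythroid iron uptake had 1 higher and 1 lower on day 1, and its mean was -0.07 ± 0.10 (adjusted p = 0.665), and on day 2 it had 2 lower with a mean of -0.39 ± 0.12 (adjusted p = 0.218). Glucose transporter Slc2a1 rose on both days (0.51 ± 0.12 and 0.59 ± 0.12), as did the oxygen sensor Egln3 (0.58 ± 0.16 and 0.51 ± 0.16), while the oxidoreductase Ero1a fell (-0.44 ± 0.11 and -0.53 ± 0.11), and the list of 10 glycolysis and hypoxia genes did not pass (adjusted p = 0.736 and 0.926). The caspase Casp2 (-0.37 ± 0.11 and -0.45 ± 0.11) and the pore-forming Bak1 (-0.33 ± 0.10 and -0.32 ± 0.10) fell on days 1 and 2, in a list of 6 apoptosis genes that did not pass (adjusted p = 0.142 and 0.0723).

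Interferon-stimulated genes did not move as 1 group before day 5. The RNA sensor Ifih1 rose on days 1 and 2 (0.59 ± 0.12 and 0.44 ± 0.12), as did Oasl2 (0.58 ± 0.13 and 0.42 ± 0.13), while Irf9 changed by -0.64 ± 0.15 on day 2 (4 mice per group). The chemokine receptor Ccr9, on the dendritic cell list, rose on days 1 and 2 (0.74 ± 0.13 and 0.77 ± 0.13), as did the adipocyte hormone Adipoq (0.53 ± 0.14 and 0.82 ± 0.14). Lists with fewer than 5 measured genes were not tested with camera. Their means on day 1 were 0.37 ± 0.09 for 3 adipocyte genes, 0.27 ± 0.07 for 4 MHC class II genes, -0.44 ± 0.09 for 4 DNA repair genes, -0.16 ± 0.06 for 3 natural killer genes, 0.03 ± 0.10 for 4 mast cell, basophil and eosinophil genes, 0.11 ± 0.09 for 3 osteoclast genes and 0.15 ± 0.09 for 2 skeletal muscle genes. In an exact permutation test of list means over mice, adjusted over all 40 lists, 3 of these passed on day 1. They were DNA repair (adjusted p = 0.0244), adipocytes (adjusted p = 0.0424) and MHC class II (adjusted p = 0.0424). The second probe of Il1b was blank in all control mice and measured in 4 day 2 mice, and the probe measured in every mouse gave 0.95 on day 1, 1.45 on day 2 and -2.21 on day 5, against 0.92, 0.91 and -1.88 for the average. Among named genes, only Nadsyn1 was measured in 5 of 5 control mice and in 0 of 5 mice of a treated group, that of day 5.

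For each count, 100 splits of the mice into groups of the same sizes were drawn, the real split included. For most counts of genes only the real split was as large. These were day 1 (real 1012, highest other 370), day 2 (1018 and 47), day 5 (139 and 18), from day 2 to 5 (1102 and 288), from day 1 to 5 (1341 and 804) and among the 4 groups (1626 and 148). That is 1 of 100, the smallest share these splits allow, without adjustment for the number of counts looked at. It argues against chance for these counts but does not exclude it. From day 1 to 2 it was 2 splits (real 111, highest other 504), without adjustment for the number of counts looked at, so chance is not excluded. A split that calls several times the real count points to a structure of these mice other than the day. That split set day 1 mice 1 and 4 and day 2 mice 2, 4 and 5 against the others. On the first principal component these lay at 0.97 to 7.31 and the others at 10.67 to 16.56. What the structure is was not tested, and it may bear on the calls of days 1 and 2 against control and on those they share. For lists on day 1, only the real split called as many (real 10, highest other 9). On day 2 it was 3 splits (9 and 11), on day 5 it was 4 (8 and 8) and from day 1 to 2 it was 3 (9 and 10), also unadjusted. Chance is not excluded for these, nor for the lists called from day 2 to 5 (5 splits, 13 and 15) and from day 1 to 5 (7 splits, 12 and 16). For shared calls the splits do not decide, since a split that calls few genes can share few. As many were shared in 1 split for days 1 and 2 (582 and 1), 1 split for days 2 and 5 (42 and 1) and 2 splits for days 1 and 5 (16 and 172). For days 1 and 5, independent lists would share 5.15 higher and 7.63 lower, so sharing by chance is not excluded.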
